A study of Mus musculus with 16 samples.

How the data were processed

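Bulk RNA sequencing was measured in 16 end-stage subcutaneous tumours grown in C57BL/6J mice. The tumours came from B16F10 cells, a mouse melanoma line, either wild-type (WT) or with low Pros1 (BdP, which the sample titles call deficient in Pros1 and another label a Pros1 knockdown). Mice received PBS or cisplatin, a platinum drug that crosslinks DNA, at 5 mg/kg in 2 rounds of 3 daily doses, starting 8 days after implantation. Each of the 4 groups held 4 libraries. The labels number the replicates but do not say whether a number marks a shared litter, day or batch, nor where each tumour came from beyond its being a separate replicate.

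The deposited values are FPKM (fragments per kilobase of gene length, scaled by sequencing depth), made by the authors from reads for which the labels name CASAVA, HISAT2 2.0.5 and featureCounts 1.5.0-p3, on the mouse build GRCm38 (mm10). The table held 54532 genes with position, length and biotype. FPKM multiplied by gene length was a whole multiple of 1 step in every library for 100% of genes, within a tolerance of 0.1 read, so the number of reads per gene and library was recovered from the step. The divisor that the step implies equalled the median-of-ratios size factor of those reads (ratio 1.00 in each library, scaled to the geometric mean), so the deposited FPKM were already scaled between libraries and were not normalised again. Gene symbols that a spreadsheet had turned to dates (27) were restored from the gene identifiers with GENCODE M21, which held 54409 of the identifiers, 53499 of them (98.3%) at the position given in the table.

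Genes with at least 1 FPKM in at least 4 libraries were tested (12319 genes, 10891 of them protein-coding). Group means were fitted to log2(FPKM + 1) in limma 3.58.1 (R 4.3.3) over all 16 libraries, with empirical Bayes moderation and a mean-variance trend. All fold changes below are on this log2(FPKM + 1) scale, which shrinks changes of genes near 0. There were 5 contrasts, namely cisplatin against PBS within each genotype, BdP against WT within each treatment, and the interaction (the cisplatin response in BdP minus that in WT). A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Errors of log2 fold changes are moderated standard errors and those of FPKM and scores are SD with n = 4.

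Gene lists were tested with camera from limma, at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. The adjusted p values of lists cover 170 tests, 34 lists in 5 contrasts. A score per library, the mean log2(FPKM + 1) over the members tested, was compared by an exact two-sided permutation test, for which 70 splits of 4 against 4 give a smallest p of 0.0286. The lists covered the Pros1-TAM-PTP1B axis, p53 targets, DNA crosslink and excision repair, cell cycle, type I interferon and interferon gamma responses, MHC class I and class II presentation, macrophages, M1-like and M2-like macrophage genes, T cells, cytotoxic effector genes, NK cells, immune checkpoints, regulatory T cells, B and plasma cells, dendritic cells, neutrophils, chemokines, NF-kB and inflammatory cytokines, melanoma and melanocyte genes, fibroblasts and matrix, endothelium and angiogenesis, hypoxia and glycolysis, oxidative phosphorylation, oxidative stress and metallothioneins, apoptosis, EMT and invasion, complement and coagulation, senescence-associated secretory genes, immediate early and dissociation genes, erythroid cells and mitochondrially encoded genes. Lists with fewer than 5 genes past the filter were not tested (skeletal muscle, skin keratinocytes, adipocytes, lymphatic endothelium and lymph node stroma, and nuclear and intron-rich transcripts). Several lists share members, so their results are not independent.

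In each contrast the genes named were the 10 protein-coding genes with the largest called change in each direction, with a mean of at least 5 FPKM in the higher group and a proper symbol (5 each way for the interaction). Where fewer than 5 passed, the 5 genes with the smallest p are named as such. Pros1, Gas6, Tyro3, Axl, Mertk and Ptpn1 were always reported, as were up to 4 members with the smallest p of each list discussed. The contrasts, lists, naming rule and alternatives, save those named as added, were chosen before the data were examined.

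The procedure was tested on simulated data with the levels and spread of all 4 groups, changed in the BdP libraries under PBS. In the contrast of BdP with WT under PBS it recovered 66% of 100 genes raised or lowered 2-fold and 89% of 100 genes changed 4-fold. It called 12 unchanged genes there and 0 in the contrast under cisplatin, which was left unchanged. A T cell list raised 1.5-fold was not called (adjusted p = 0.5) and one raised 2-fold was (adjusted p = 2.72e-05), with 0 of the other 33 lists called either time. Genes were simulated independently of each other, so false calls of lists whose members move together were not tested.

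Alternatives tried were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 FPKM, TPM, median-of-ratios scaling, quantile normalization, the replicate number as a block, a fit on the 8 libraries compared, array weights, no trend, protein-coding genes only, removal of Xist and chromosome Y genes, a covariate for leukocyte content (mean log2 level of Ptprc, Coro1a, Laptm5 and Lcp1) or skeletal muscle, and leaving out each library in turn. Fits with limma-voom on the recovered reads, without the libraries richest in mitochondrial reads, and with a covariate for host sex were added after the data were seen. So was the use of the leukocyte covariate in the camera tests of lists. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.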

Results

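RNA was measured in 16 tumours in a design of genotype by treatment. There were 4 libraries each of WT tumours under PBS, WT tumours under cisplatin, BdP tumours under PBS and BdP tumours under cisplatin. Reads assigned to genes ran from 10051843 (WT PBS 1) to 27055771 (BdP cisplatin 1), with a median of 21119708. Mitochondrial transcripts took 76.9% of the reads of WT PBS 1, which left 2322202 other reads there. They took 12.2% in WT cisplatin 3 and 21.7% in WT cisplatin 4, against 2.03% to 5.06% in the other 13 libraries. Haemoglobin transcripts took 15.5% of reads in WT PBS 2 and 0.002% in BdP cisplatin 1 and 2. Correlations of log2 values within groups ran from 0.882 to 0.975, with a minimum of 0.896 without WT PBS 1. Transcripts of Xist and of the Y chromosome showed hosts of both sexes in each group. The Y-positive libraries were WT PBS 4, WT cisplatin 1 and 2, BdP PBS 3 and 4, and BdP cisplatin 1 and 2.

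**Figure D1:**
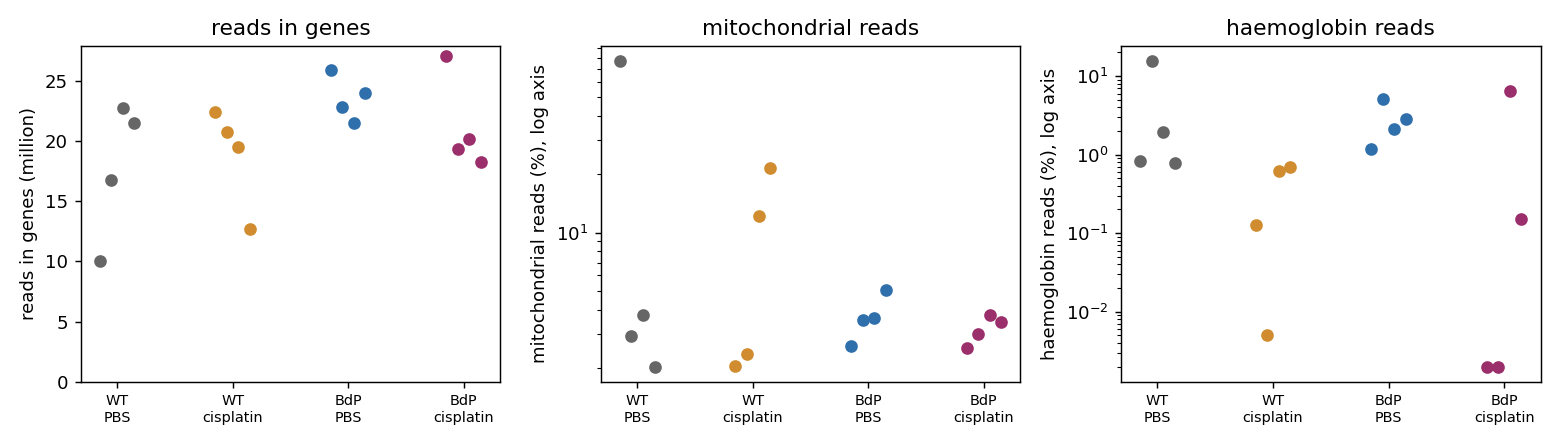
Reads in genes, mitochondrial reads (%, log axis) and haemoglobin reads (%, log axis) in each library, 4 points per group. WT PBS 1 had the lowest total, 10051843 reads, and 76.9% mitochondrial reads.

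Pros1, the gene of protein S, an anticoagulant and a ligand of the TAM receptors (Tyro3, Axl and Mertk), was lower in every BdP library than in any WT library. Under PBS it measured 9.77, 4.79, 5.89 and 5.42 FPKM in the WT tumours (6.47 ± 2.25, SD, n = 4) and 1.61, 1.59, 1.58 and 1.24 FPKM in the BdP tumours (SD 0.179). Under cisplatin the WT tumours measured 10.4, 11.5, 7.78 and 11.4 FPKM (10.3 ± 1.74) and the BdP tumours 2.39, 2.21, 2.52 and 1.73 FPKM (2.21 ± 0.345). Pros1 (ENSMUSG00000022912, chromosome 16 from 62854307 to 62929346, GRCm38) fell by 1.54 ± 0.17 on the log2 scale under PBS (adjusted p = 0.00092) and by 1.80 ± 0.17 under cisplatin (adjusted p = 0.000103). The exact two-sided permutation p was 0.0286 in both, the smallest that 4 against 4 can give. Both calls were kept when any 1 library was left out, with adjusted p of at most 0.00543. Neither passed in TPM, where they were -0.96 (adjusted p = 0.359) and -1.91 (adjusted p = 0.216).

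Cisplatin did not pass the test for Pros1 in WT tumours, with a log2 fold change of 0.62 ± 0.17 (adjusted p = 0.546, or 0.0264 over the list alone), or in BdP tumours (0.36 ± 0.17, adjusted p = 1). Taken alone, without adjustment over genes, Pros1, Gas6 and Mertk had an exact two-sided permutation p of 0.0286 with cisplatin in BdP tumours, and Pros1 0.0571 in WT tumours. None of the TAM receptor genes Tyro3, Axl and Mertk, their second ligand Gas6, or Ptpn1, the gene of the phosphatase PTP1B named in the title of the series, was called in any of the 5 contrasts. Gas6 was at 4.08 ± 2.69 FPKM in WT and 4.04 ± 1.02 FPKM in BdP tumours under PBS, and at 1.92 ± 0.776 and 1.99 ± 0.746 FPKM under cisplatin (n = 4 each). The Gas6 change with cisplatin was -0.69 ± 0.31 in WT and -0.76 ± 0.31 in BdP tumours (adjusted p = 0.635 and 1). Axl spread widely, from 2.79 ± 1.04 FPKM in WT tumours under cisplatin to 17.6 ± 11.9 FPKM in BdP tumours under PBS. Its largest difference, BdP over WT under cisplatin, was 1.55 ± 0.67 (adjusted p = 0.33). Ptpn1 stayed between 10.5 ± 1.12 and 12.7 ± 3.63 FPKM in the 4 groups. The Pros1-TAM-PTP1B list as a whole was not called in any contrast (smallest adjusted p = 0.196, 10 genes).

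**Figure D2:**
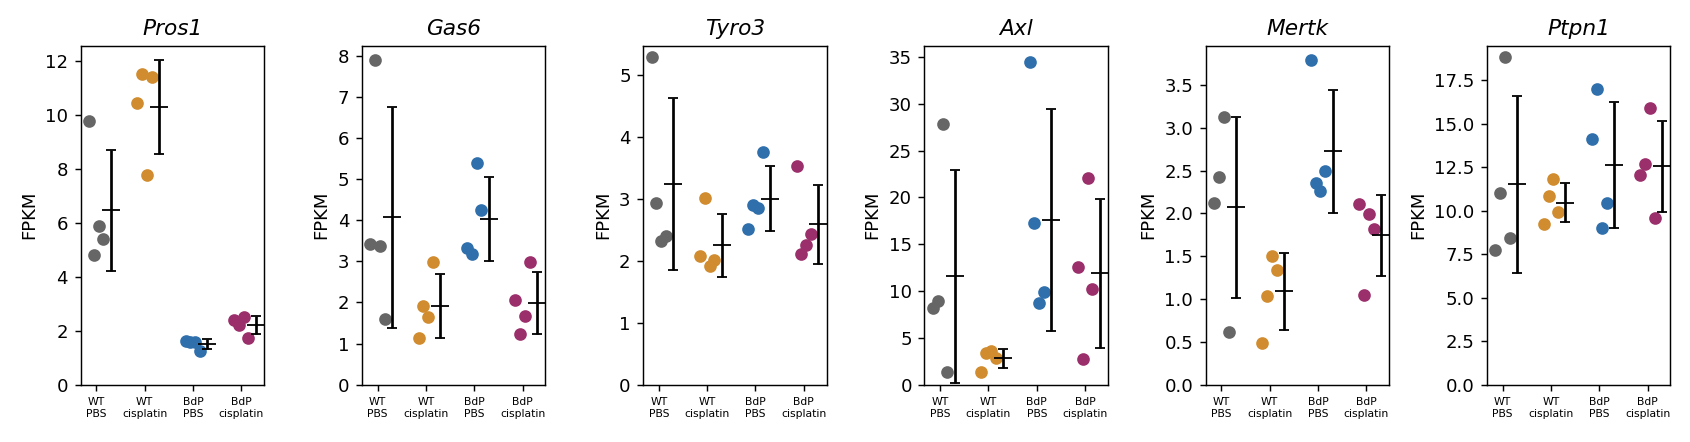
FPKM of Pros1, Gas6, Tyro3, Axl, Mertk and Ptpn1 per library, with the mean and SD of each group (n = 4). All 8 BdP libraries lay between 1.24 and 2.52 FPKM of Pros1, and all 8 WT libraries between 4.79 and 11.5 FPKM.

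The comparison of cisplatin with PBS in WT tumours asks what the drug left behind in tumours that make Pros1. Targets of p53, the transcription factor that responds to DNA damage, were higher under cisplatin as a group. Of 28 targets, 23 had a positive change, with a median of 0.30 (adjusted p = 0.000312, and adjusted p = 1 with an estimated correlation). Without WT PBS 1 the median was 0.15. Their score was 3.49 ± 0.0400 against 3.18 ± 0.239 (n = 4, exact two-sided permutation p = 0.0286). The members with the smallest p were Psrc1 (0.91 ± 0.26), Bbc3, a pro-apoptotic BH3-only gene (0.79 ± 0.25), Trp53inp1 (0.64 ± 0.29) and Cdkn1a, the cell cycle inhibitor p21 (0.57 ± 0.28). None of the 28 was called alone, either over all genes or adjusted over the list alone. Lamb1, a laminin chain of basement membranes (ENSMUSG00000002900, chromosome 12 from 31265234 to 31329644), was the 1 gene called. It rose from 2.04 ± 0.427 to 5.18 ± 0.310 FPKM (log2 fold change 1.04 ± 0.14, adjusted p = 0.0275). Ndrg2 (0.80), Sema3f (0.93), Diras1 (1.03) and Prickle1 (0.81), next by p, were not called (adjusted p = 0.151 for each).

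Interferon-related groups were lower under cisplatin in WT tumours. The interferon gamma list, with the GTPases Gbp4, Iigp1 and Tgtp1 and the immunoproteasome subunit Psmb10 as its smallest p, had a median of -0.83 with 22 of 24 genes negative (adjusted p = 0.000682, and adjusted p = 1 with an estimated correlation). The type I interferon list (median -0.43, Rsad2 -0.98 ± 0.42 and Isg15 -1.34 ± 0.66, adjusted p = 0.000979), the MHC class I list (median -0.41, adjusted p = 0.00607) and the immune checkpoint list (median -0.39, adjusted p = 0.0395) went the same way. All 4 had an adjusted p = 1 with an estimated correlation. None of these 4 list scores differed by the exact two-sided permutation test (p = 0.371, 0.4, 0.571 and 0.6). The 4 calls rested on WT PBS 3. Without it adjusted p was 0.665 for interferon gamma, 0.844 for type I interferon, 0.737 for MHC class I and 0.86 for checkpoints, whose median was then 0.05. Without WT cisplatin 1 the MHC class I list was lost too, and the checkpoint list was also lost without WT PBS 2 or WT cisplatin 1 or 2.

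Erythroid genes were lower, with a median of -3.90 and 9 of 9 genes negative. This list and the 5 others in this paragraph had an adjusted p = 1 with an estimated correlation. Among them was the heme synthesis gene Alas2 (-3.90 ± 1.73). The list had an adjusted p = 6.42e-06 and an exact two-sided permutation p of 0.0571. Nuclear genes of oxidative phosphorylation were lower by little (median -0.18, 24 of 26 negative, adjusted p = 0.00045). Its median was -0.005 (adjusted p = 0.855) without the 3 libraries richest in mitochondrial reads. Neutrophil genes were higher in 9 of 9 (median 0.67, adjusted p = 0.00242, exact two-sided permutation p = 0.229), with the calprotectin genes S100a8 at 0.87 ± 0.41 and S100a9 at 0.94 ± 0.45. B and plasma cell genes were higher too (median 0.62, adjusted p = 0.00825, exact two-sided permutation p = 0.229), and Igha alone passed over the list alone (adjusted p = 0.0104). Also higher were the lists of immediate early genes (median 0.43, adjusted p = 0.0111) and NF-kB and inflammatory cytokines (median 0.33, Il1b 1.40 ± 0.77, adjusted p = 0.0201). Their scores did not differ by the exact two-sided permutation test (p = 0.6 and 0.371), nor did that of oxidative phosphorylation (p = 0.314).

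By limma, 1 gene was called in WT tumours, with 953 at an unadjusted p below 0.05. Of 34 lists 11 were called, 5 higher and 6 lower. All 11 had an adjusted p = 1 with an estimated correlation. Lamb1 lost its call in 9 of 16 runs that left out 1 library, with adjusted p up to 0.209 (without WT PBS 2 or 3, WT cisplatin 1, 2, 3 or 4, BdP PBS 1 or 3, or BdP cisplatin 1). The p53, oxidative phosphorylation and erythroid lists kept theirs in all 16 runs, with a median of -0.10 for oxidative phosphorylation without WT PBS 1, -0.12 without WT cisplatin 4 and -0.29 without WT PBS 3. The neutrophil list was lost without WT PBS 4 or WT cisplatin 4 (adjusted p up to 0.16), and the B cell list without WT PBS 4 or WT cisplatin 3 (up to 0.344). Also lost were the immediate early list without WT PBS 1 or WT cisplatin 3 or 4 (up to 0.553) and the NF-kB list without WT PBS 1 or 4 or WT cisplatin 3 or 4 (up to 0.471). The immediate early and NF-kB lists also turned without the 3 libraries richest in mitochondrial reads, to -0.37 (adjusted p = 0.000107) and -0.28 (adjusted p = 0.0757). The immediate early list turned to -0.14 without WT PBS 1 alone.

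The same comparison in BdP tumours asks whether the drug left similar changes where Pros1 was low. The p53 targets were again called as a group (median 0.10, 18 of 28 positive, adjusted p = 0.00329, and adjusted p = 1 with an estimated correlation). Their median was 0.01 without BdP cisplatin 2 and 0.06 without BdP PBS 3. It was 0.15 and 0.17 without BdP PBS 1 and 2, and 0.16 and 0.17 without BdP cisplatin 1 and 3. They had a score of 3.39 ± 0.150 against 3.23 ± 0.104 (exact two-sided permutation p = 0.143). Cdkn1a was 1.06 ± 0.28 higher and passed over the list alone (adjusted p = 0.0492), followed by Ccng1 (0.81 ± 0.26) and Phlda3 (0.81 ± 0.27). Cell cycle genes were higher (median 0.12, 23 of 32 positive, adjusted p = 0.000312), with Kif20a at 0.56 ± 0.17 and the mitotic kinase Plk1 at 0.40 ± 0.13. The cell cycle list and the 2 that follow had an adjusted p = 1 with an estimated correlation. Higher too were genes of oxidative phosphorylation (median 0.15, 24 of 26 positive, adjusted p = 9.1e-05) and of hypoxia and glycolysis (median 0.17, 19 of 23 positive, adjusted p = 0.000801). The exact two-sided permutation p of the scores was 0.114 for cell cycle, 0.257 for oxidative phosphorylation and 0.486 for hypoxia. Adm, the adrenomedullin gene that hypoxia induces, passed over the list alone (0.69 ± 0.17, adjusted p = 0.0275).

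Erythroid genes were lower with cisplatin in BdP tumours (median -4.005, adjusted p = 0.000523), with Hba-a2 at -5.42 ± 1.93. Their score did not differ by the exact two-sided permutation test (p = 0.143). BdP cisplatin 3 stood apart, with a score of 8.64 against 6.36 to 7.87 under PBS and 6.46% haemoglobin reads. Immediate early genes were lower in 21 of 22 (median -0.47, adjusted p = 1.42e-05), with the heat shock genes Hspa1b at -2.04 ± 0.58 and Dnajb1 at -0.63 ± 0.21. B and plasma cell genes were lower (median -0.68, adjusted p = 0.00479), and Igha passed over the list alone (adjusted p = 0.00144). The B cell median was near 0 without BdP PBS 2 (0.025) or BdP cisplatin 1 (0.023), and was -1.41 without BdP PBS 3 and -1.33 without BdP cisplatin 2. Macrophage genes were lower in 18 of 19 (median -0.58, adjusted p = 0.0139), with the complement gene C1qa at -1.20 ± 0.89 and Ms4a7 at -0.81 ± 0.51. NF-kB genes (median -0.33, adjusted p = 0.0258) and melanocyte genes (median -0.14, adjusted p = 0.00657) were lower too. The lineage factor Mitf was at -0.53 ± 0.17 and Slc24a5 at -0.49 ± 0.16. None of these scores passed the exact two-sided permutation test (p = 0.0571 for immediate early genes, 0.543 for B cells and for macrophages, 0.371 for NF-kB and 0.229 for melanocyte genes). These lists, too, had an adjusted p = 1 with an estimated correlation. The melanocyte list holds genes of the tumour cells themselves.

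No single gene was called in BdP tumours. Limma gave 0, with 542 at an unadjusted p below 0.05. The genes with the smallest p, none of them called, were Stxbp3-ps (-0.93, adjusted p = 0.0839), the T cell receptor segment Trbj1-2 (adjusted p = 0.0839), Igha (-1.20, adjusted p = 0.369), the protein C receptor gene Procr (-0.68, adjusted p = 0.524) and Tubb3 (0.76, adjusted p = 0.773). Trbj1-2 was at 0 in both PBS groups, so no fold is given, and at 3.11 ± 1.46 FPKM in BdP tumours under cisplatin. In so short a segment a few reads give such values, so it lies near the floor. Of 34 lists, 10 were called (4 higher, 6 lower), and all had an adjusted p = 1 with an estimated correlation. The p53, cell cycle, hypoxia, immediate early and erythroid lists kept their calls with any 1 library left out. The cell cycle median was 0.08 without BdP PBS 1, and the hypoxia median 0.085 without BdP PBS 4. The macrophage list was lost without BdP PBS 1 or 2 or BdP cisplatin 2 (adjusted p up to 0.909), and the B cell list without BdP PBS 1 or 2 or BdP cisplatin 1 or 3 (up to 0.497). Also lost were the NF-kB list without BdP PBS 1 or 2 or BdP cisplatin 1 or 2 (up to 0.577), the melanocyte list without BdP PBS 3 or 4 or BdP cisplatin 2 (up to 0.132) and the oxidative phosphorylation list without BdP PBS 4 (0.0661).

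Without the drug, single genes of varied function differed between BdP and WT tumours. Sparc, a secreted matrix glycoprotein (ENSMUSG00000018593, chromosome 11 from 55394500 to 55423183), fell by 1.11 ± 0.17 on the log2 scale, from 137 ± 31.4 to 62.3 ± 7.03 FPKM (n = 4, adjusted p = 0.007). Loxl2, a lysyl oxidase that crosslinks collagen, fell by 1.23 ± 0.15 (8.40 ± 1.58 to 2.98 ± 0.523 FPKM, adjusted p = 0.000985). Jph2, a junctophilin that ties the endoplasmic reticulum to the plasma membrane (ENSMUSG00000017817, chromosome 2 from 163336242 to 163397993), had the smallest p and fell by 1.57 ± 0.12, from 7.75 ± 1.07 to 1.95 ± 0.303 FPKM (adjusted p = 3.11e-05). Myl9, a myosin light chain, fell by 2.37 ± 0.46 from 10.9 ± 9.27 to 1.04 ± 0.752 FPKM (adjusted p = 0.0267). Also lower were the homeobox gene Hoxd13 (-1.65), Pafah1b3 (-1.16), Specc1 (-1.10), Mcts2 (-1.04) and the RNA cyclase Rtca (-0.89, adjusted p = 0.00435).

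Higher in BdP tumours under PBS was Hgsnat, a lysosomal enzyme of heparan sulfate breakdown (ENSMUSG00000037260, chromosome 8 from 25944453 to 25976753), which rose by 1.44 ± 0.21, from 57.1 ± 11.2 to 158 ± 39.7 FPKM (adjusted p = 0.00577). Pcna-ps2 (1.27), Tcf7l1, a repressor in the Wnt pathway (1.09), Adgra2 (1.07), Coq8a of coenzyme Q synthesis (1.06), Nipal3 (1.05), Tmco6 (1.02), Sbno2 (0.95), Pdcd4 (0.86) and Mtss1, a regulator of actin (0.84), were higher too. Pcna-ps2 and Mcts2 are copies of Pcna and Mcts1, and reads of the copies were not told apart here. The cell cycle list was lower as a group (27 of 32 negative, median -0.22, adjusted p = 2.14e-05, exact two-sided permutation p = 0.0571, and adjusted p = 1 with an estimated correlation). Ccna2, the cyclin A2 gene on chromosome 3, fell by 0.48 ± 0.08 (adjusted p = 0.0132), and 3 members (Ccna2, Tpx2 and Aurka) were lower adjusted over the list alone.

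Lymphoid and inflammatory groups were higher in BdP tumours under PBS, with a wide spread between tumours. The B and plasma cell list rose by a median of 2.32 with 16 of 16 genes positive (adjusted p = 1.51e-07, exact two-sided permutation p = 0.0571). It had an adjusted p = 1 with an estimated correlation, as had each list in this paragraph. Igha, the heavy chain of IgA, was called (1.71 ± 0.23, from 0.0208 ± 0.0326 to 2.35 ± 0.364 FPKM, adjusted p = 0.00245). Igkc (4.75 ± 1.46) and Jchain (1.81 ± 0.62) were among 14 members higher adjusted over the list alone. T cell genes were higher in 20 of 20 (median 1.10, Trac 2.35 ± 1.04, adjusted p = 0.000136, exact two-sided permutation p = 0.2). Immediate early genes (median 1.07, Jund 0.97 ± 0.25, adjusted p = 2.02e-05) and NF-kB genes (median 0.87, Relb 0.59 ± 0.25, Cxcl2 1.88 ± 0.80, adjusted p = 0.000271) were higher. So were MHC class II (median 1.92, adjusted p = 0.00242), cytotoxic effectors (0.92, adjusted p = 0.00825), NK cells (0.50, adjusted p = 0.0157), and checkpoints (0.69, adjusted p = 0.00825). The others higher were chemokines (0.93, adjusted p = 0.0175), type I interferon (0.50, adjusted p = 0.00726), and M1-like (0.62, adjusted p = 0.0038) and M2-like macrophage genes (0.62, adjusted p = 0.0101). None of these scores passed the exact two-sided permutation test (p = 0.0571 for immediate early genes, 0.171 for NF-kB and MHC class II, 0.2 for M1-like genes, 0.229 for cytotoxic effectors and checkpoints, 0.286 for NK cells, 0.314 for chemokines and M2-like genes and 0.571 for type I interferon). The leukocyte score (Ptprc, Coro1a, Laptm5 and Lcp1) was 4.96 ± 1.22 in BdP and 3.28 ± 1.76 in WT tumours (exact two-sided permutation p = 0.171). Kit, the receptor of the melanocyte lineage, rose by 1.18 ± 0.24 (adjusted p = 0.0338), while the melanocyte list was not called (median 0.03, adjusted p = 0.919).

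Under PBS limma called 122 genes, 51 higher and 71 lower in BdP tumours (2377 at an unadjusted p below 0.05), and 15 of 34 lists, 12 higher and 3 lower. The lists had an adjusted p = 1 with an estimated correlation. The gene count ran from 25 (without BdP PBS 4) to 356 (without WT PBS 3), with 79 without WT PBS 1, 65 without WT PBS 4, 47 without BdP PBS 1 and 75 without BdP PBS 3. It was 3 in a fit on these 8 libraries alone. In TPM the median of all genes shifted by 0.82, and 42 of the 122 genes changed sign. With leukocyte content as a covariate 23 genes were called, and 9 of the lists higher here had medians below 0. Of the 20 named genes, 8 (Hgsnat, Sbno2, Mtss1, Jph2, Pros1, Loxl2, Sparc and Rtca) were called in all 16 runs that left out 1 library. Without BdP PBS 4, 12 of the 20 lost the call, 9 without BdP PBS 1, 8 without WT PBS 1 or 4 and 7 without BdP PBS 3. Among the same 12, 4 did so without BdP PBS 2, 3 without WT PBS 2, 2 without BdP cisplatin 1, and 1 each without WT cisplatin 1, 3 or 4 or BdP cisplatin 4 (adjusted p up to 0.142). The cell cycle, T cell, B cell, NF-kB and immediate early lists kept their calls, and the other 10 did not. Medians were 0.62 for T cells and 0.56 for NF-kB without BdP PBS 2, and 0.47 for immediate early genes without WT PBS 1. Lost were 8 of the 15 without WT PBS 4, 7 without BdP PBS 2, 6 without BdP PBS 1, 4 without WT PBS 1, 2 without WT PBS 2 and 1 without BdP PBS 3 or 4 (adjusted p up to 0.643). The lower lists of oxidative phosphorylation (median -0.17, adjusted p = 0.0175) and of mitochondrially encoded genes (median -1.61, adjusted p = 0.0345) were lost without WT PBS 1 (adjusted p up to 0.28 and 0.446). The mitochondrially encoded list turned to a median of 0.31 there, so its direction rested on that library, and it was also lost without BdP PBS 1, 2 or 3.

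Under cisplatin the interferon groups separated the genotypes. The interferon gamma list was higher in BdP tumours in 24 of 24 genes (median 1.24, adjusted p = 1.25e-07). It had an adjusted p = 1 with an estimated correlation, as had each list called under cisplatin. Its scores were 2.92 ± 0.619 against 1.57 ± 0.489 (n = 4, exact two-sided permutation p = 0.0286), with the lowest BdP library (2.35) above the highest WT library (2.16). Its smallest p belonged to Nlrc5, the activator of MHC class I genes (1.15 ± 0.44), Serpina3g (2.33 ± 0.91), Gbp9 (1.23 ± 0.49) and Igtp (2.14 ± 0.89). The type I interferon list was higher in 28 of 28 genes (median 0.82, the RNA sensor gene Ddx58 1.01 ± 0.32, Irf9 0.81 ± 0.26 and Bst2 1.21 ± 0.47, adjusted p = 1.25e-07, exact two-sided permutation p = 0.0286). MHC class I genes were higher in 19 of 21 (median 1.02, the trimming peptidase Erap1 0.98 ± 0.39, adjusted p = 5.66e-05, exact two-sided permutation p = 0.0286). None of these members was called alone, either over all genes or adjusted over the list alone.

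**Figure D3:**
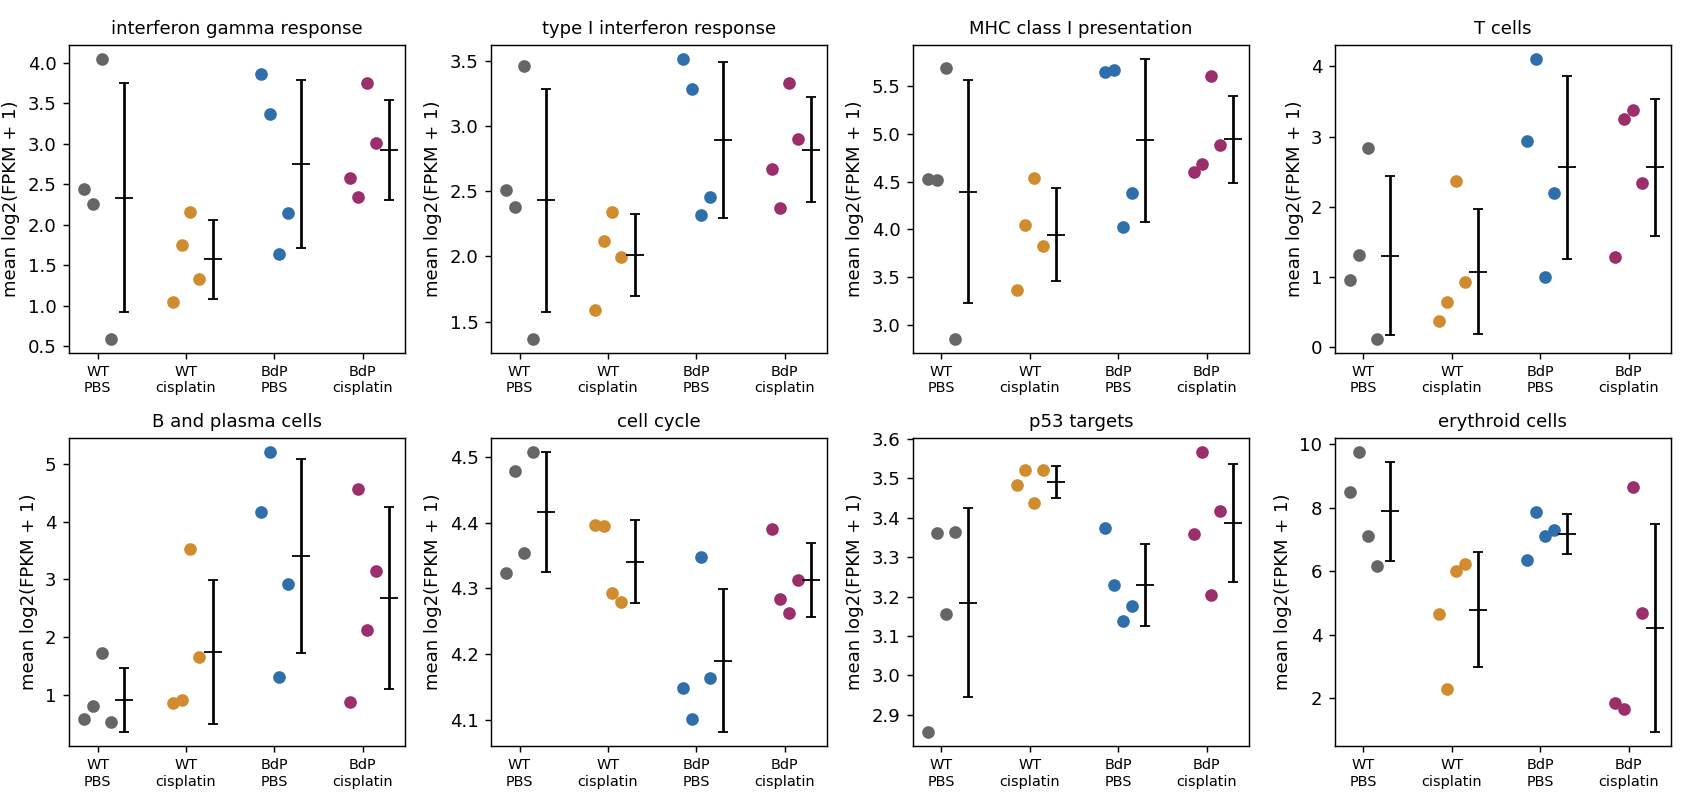
Score of 8 gene lists per library (mean log2(FPKM + 1) over the members tested), with the mean and SD of each group (n = 4). Under cisplatin the interferon gamma scores of BdP libraries (at least 2.35) lay above those of WT libraries (at most 2.16), while under PBS the genotypes overlapped.

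Markers of lymphocytes went the same way under cisplatin. NK cell genes were higher in BdP tumours in 17 of 17 (median 0.97, Klrb1c 1.29 ± 0.48, adjusted p = 1.69e-06, exact two-sided permutation p = 0.0286). T cell genes were higher in 20 of 20 (median 1.54, Cd6 1.53 ± 0.61, the kinase Zap70 1.59 ± 0.64, Thy1 2.07 ± 0.85, adjusted p = 3.66e-07, exact two-sided permutation p = 0.0857), as were cytotoxic effectors in 15 of 15 (median 1.81, the perforin gene Prf1 2.13 ± 0.86, Il2rb 2.31 ± 0.87, adjusted p = 2.25e-05, exact two-sided permutation p = 0.0571). MHC class II (median 1.86, Cd74 2.69 ± 1.21, adjusted p = 0.000344), checkpoints (median 0.79, Cd276 0.46 ± 0.14, Cd47 0.61 ± 0.19, adjusted p = 2.14e-05) and regulatory T cells (median 1.20, Foxp3 1.03 ± 0.49, adjusted p = 0.00658) were called higher. So were dendritic cells (median 1.07, adjusted p = 0.0457), M1-like (0.64, adjusted p = 0.0487) and M2-like macrophage genes (0.65, adjusted p = 0.0186). With the leukocyte score as a covariate these 3 turned, to -0.09, -0.33 (adjusted p = 0.0499) and -0.10. The dendritic list had 10 genes tested, as its members Flt3, Zbtb46, Xcr1, Clec9a, Siglech and Snx22 failed the filter. Fscn1, another member, was called lower in BdP tumours. The regulatory T cell list had 5 genes tested. The exact two-sided permutation p was 0.0286 for regulatory T cells, 0.0571 for MHC class II, 0.0857 for checkpoints and dendritic cells, 0.343 for M1-like and 0.2 for M2-like genes. The general macrophage list was not called (median 0.69, adjusted p = 0.0612), and B and plasma cells were not (median 1.08, adjusted p = 0.0687). Oxidative phosphorylation genes were higher by a median of 0.17 (24 of 26 positive, adjusted p = 0.0038), and Sdhc was called (0.53 ± 0.12, adjusted p = 0.0423). The score difference of the list was 0.172, or 0.071 without the libraries rich in mitochondrial reads, 0.34 within Xist-positive and 0.004 within Y-positive libraries. The list call was lost without the libraries rich in mitochondrial reads, and its median was 0.11 without WT cisplatin 4 and 0.10 without BdP cisplatin 3. The leukocyte score was 4.92 ± 0.679 in BdP and 3.20 ± 1.10 in WT tumours (exact two-sided permutation p = 0.0571). With it as a covariate the interferon gamma difference between scores went from 1.35 to 0.257 ± 0.457, that of type I interferon from 0.807 to 0.156 ± 0.282 and that of MHC class I from 0.997 to 0.027 ± 0.308. Those of lymphoid lists went from 1.48 to 0.094 ± 0.337 (T cells), from 1.24 to 0.321 ± 0.444 (NK cells), from 1.54 to 0.271 ± 0.513 (cytotoxic effectors) and from 1.34 to 0.262 ± 0.426 (regulatory T cells), and that of MHC class II from 1.88 to 0.052 ± 0.353.

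Single genes differed between the genotypes under cisplatin too. Lamb1 (-2.04 ± 0.14, from 5.18 ± 0.310 to 0.518 ± 0.265 FPKM) and Ndrg2, a stress-responsive gene (-2.00 ± 0.14, chromosome 14 from 51905271 to 51914158), shared the smallest adjusted p of 1.94e-06. Sparc fell by 1.51 ± 0.17, from 182 ± 15.6 to 64.4 ± 14.2 FPKM (adjusted p = 0.000236). Myl9 fell by 3.35 ± 0.46 (adjusted p = 0.00175), the galectin gene Lgals7 by 2.85 ± 0.42, the small heat shock gene Hspb1 by 2.78 ± 0.56. Other genes lower were the linker histone H1fx (-2.45 ± 0.25), the hypoxia-responsive Ndufa4l2 (-2.37 ± 0.28) and the actin-bundling Fscn1 (-1.90 ± 0.37). Higher were Pcna-ps2 (1.85 ± 0.23), Hgsnat (1.504 ± 0.21, 55.4 ± 17.2 to 155 ± 20.6 FPKM, adjusted p = 0.00181) and the decoy receptor gene Tnfrsf11b (1.30). Also higher were Zdhhc2 (1.07), the glutathione transferase Gsta4 (1.04), Padi2 (1.03), Chsy1 (0.96), Smpdl3b (0.95), Hip1r (0.92) and Galnt6 (0.88).

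Under cisplatin limma called 132 genes, 43 higher and 89 lower in BdP tumours (1704 at an unadjusted p below 0.05), and 13 of 34 lists, all higher. The lists had an adjusted p = 1 with an estimated correlation. The gene count ran from 50 (without WT cisplatin 1) to 310 (without WT PBS 1), with 58 and 55 without WT cisplatin 3 and 4 and 62, 62, 68 and 51 without BdP cisplatin 1, 2, 3 and 4. It was 7 with the muscle covariate, 15 in TPM, 77 with the leukocyte covariate, 76 with a filter of 5 FPKM, 55 without the libraries rich in mitochondrial reads, 251 in a fit on these 8 libraries and 943 with array weights. The muscle covariate averages a list with fewer than 5 genes past the filter, so it rests mostly on genes near 0. Of the 20 named genes, 12 (Pcna-ps2, Hgsnat, Padi2, Smpdl3b, Myl9, Lgals7, H1fx, Ndufa4l2, Lamb1, Ndrg2 and Pros1 among them) were called in all 16 runs. Without WT cisplatin 1 or 4 or BdP cisplatin 1 or 4, 8 of the 20 lost the call, and 7 without WT cisplatin 3 or BdP cisplatin 2. Among the same 8, 4 did so without BdP cisplatin 3 or BdP PBS 3, 3 without WT cisplatin 2, WT PBS 2 or 4 or BdP PBS 4, and 2 without WT PBS 3 or BdP PBS 1 or 2 (adjusted p up to 0.159). Of the lists, regulatory T cells were lost without BdP cisplatin 3 (0.0659), M2-like genes without WT cisplatin 1 or BdP cisplatin 3 or 4 (up to 0.221). Also lost were M1-like genes without WT PBS 1 or 2, WT cisplatin 1 or 2, BdP PBS 4 or BdP cisplatin 3 or 4 (up to 0.438), and dendritic cells without WT PBS 1, WT cisplatin 1 or 2, BdP PBS 1 or 4 or BdP cisplatin 3 or 4 (up to 0.134). The other 9 kept their calls, with medians of 0.63 for NK cells and 0.52 for checkpoints without BdP cisplatin 3.

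The genotype contrasts under PBS and cisplatin, which share no library, called 39 genes in common. Of these, 13 were higher in both (0.18 by chance, Fisher's exact test, one-sided p = 6.66e-22) and 26 lower in both (0.51 by chance, p = 5.33e-39), with 0 called in opposite directions. The chance counts and p values assume independent genes and calls. Both contrasts share the estimate of spread per gene, and genes moved together along chromosomes, so these values overstate the evidence. The shared genes include Pros1, Sparc, Loxl2, Jph2, Myl9, Hoxd13, Ndrg2, Ndufa4l2, Lamb1 and H1fx (lower) and Hgsnat, Mtss1, Lifr and Pdk2 (higher). TPM moved the median of all genes by 0.82 under PBS and 0.15 under cisplatin, and with that shift 10 of the 39 turned from lower to higher under PBS and 0 under cisplatin. Across all genes tested, which are not independent replicates, the contrasts correlated with r = 0.587, against 0.09 for the 2 cisplatin contrasts.

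Called genes were unevenly placed on the chromosomes, a comparison chosen after the values were seen. Among 10547 autosomal protein-coding genes tested, chromosome 3 held 4.95% of genes but 17 of 68 lower calls under PBS (25%) and 18 of 82 under cisplatin (22%). Rtca and Ccna2 lie there. Chromosome 18 and the part of chromosome 8 from 3122061 to 84000409 held 5.61% of genes but 14 of 43 higher calls under PBS (32.6%). Under cisplatin it was 12 of 38 (31.6%). Hgsnat, Adgra2, Zdhhc2 and Tmco6 lie there. The median change of the 522 genes on chromosome 3 was -0.14 under PBS and -0.20 under cisplatin. That of the 317 genes on the proximal part of chromosome 8 was 0.23 and 0.24, and that of the 275 genes on chromosome 18 was 0.20 and 0.27. No p is given for these segments, since they were picked for their shift in the same libraries.

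**Figure D4:**
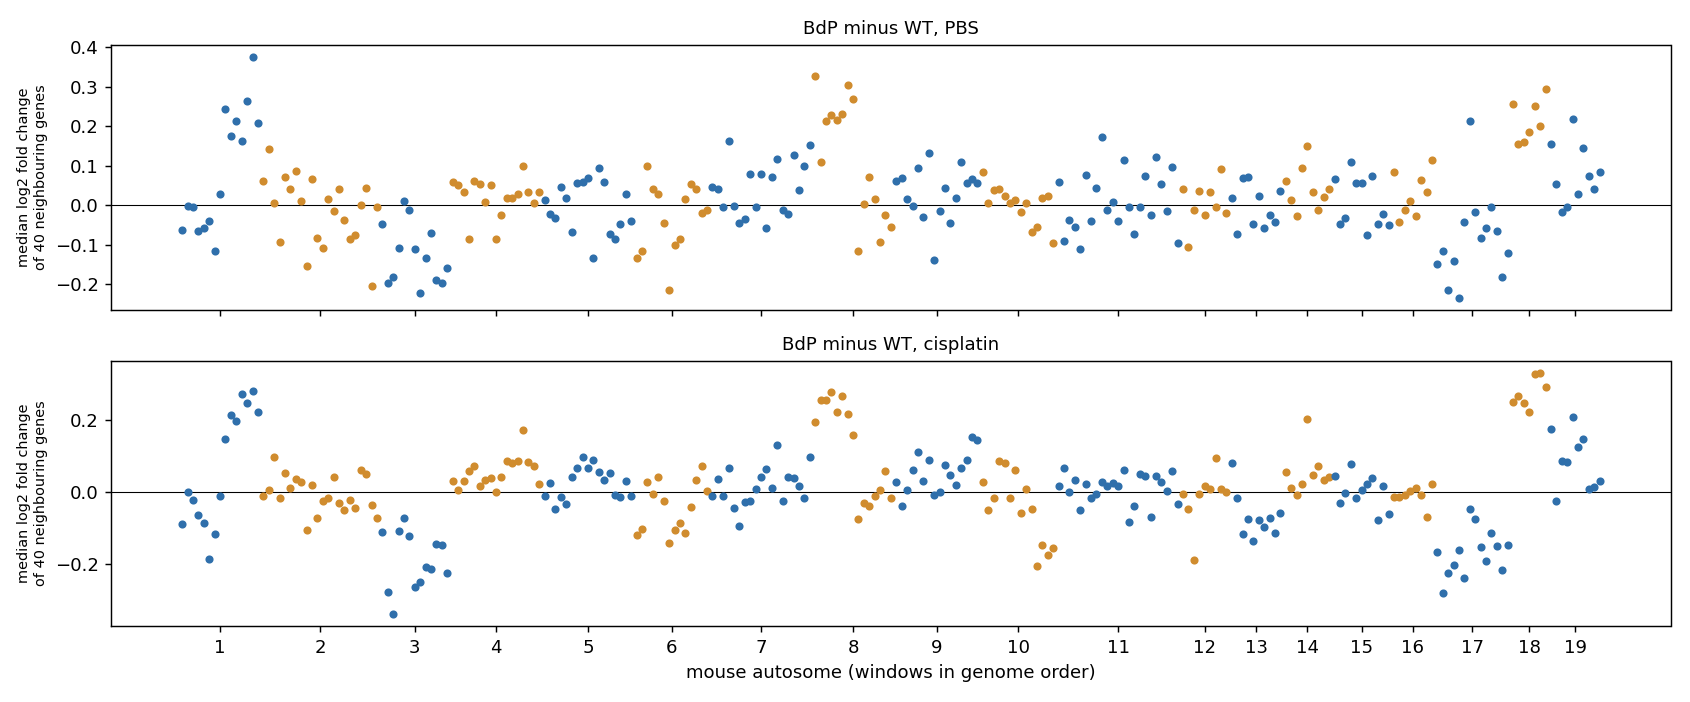
Median log2 fold change (BdP minus WT) in 263 windows of 40 neighbouring autosomal genes, in genome order, under PBS and under cisplatin. Each point is a window. Chromosome 3 lay below 0 (median -0.14 and -0.20) and chromosome 18 above it (0.20 and 0.27) in both.

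The interaction asks whether cisplatin acted differently in BdP and WT tumours. By limma 0 genes were called, with 691 at an unadjusted p below 0.05. The smallest p belonged to Igha (-2.17, adjusted p = 0.0795), the iron exporter gene Slc40a1 (-1.31, adjusted p = 0.31), Gm16199 (2.15, adjusted p = 0.395), 4930579G24Rik (0.64, adjusted p = 0.395) and Sema3f (-1.15, adjusted p = 0.486). By camera 9 of 34 lists were called, 5 with a higher response in BdP tumours and 4 with a lower one, and all had an adjusted p = 1 with an estimated correlation. No list passed when the treatment labels were permuted within genotype, where the smallest permutation p (two-sided) was 0.0314 for the cell cycle list (0.965 after adjustment). Interferon gamma genes, called higher in BdP than WT under cisplatin but not under PBS (adjusted p = 0.115), had a permutation p of 0.344 for the difference between treatments.

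The balance of macrophage genes, which the series title makes a question, was measured as the M1-like minus the M2-like score (17 and 20 genes). It was -0.07 ± 0.31 in WT tumours under PBS, 0.05 ± 0.26 in WT under cisplatin, 0.21 ± 0.48 in BdP under PBS and -0.03 ± 0.35 in BdP under cisplatin (n = 4 each). No contrast passed the exact two-sided permutation test (p = 0.543 for cisplatin in each genotype, 0.4 for genotype under PBS, 0.743 under cisplatin, and 0.32 for the interaction, by permutation). M1-like genes such as Cd40 (1.08 ± 0.47 under PBS) and Irf5 (1.52 ± 0.67 under cisplatin) and M2-like genes such as Il4ra (1.08 ± 0.62 under PBS) and Mgl2 (under cisplatin) were higher in BdP tumours together, none of them called alone. Both lists lost their calls with an estimated correlation, and their scores had an exact two-sided permutation p of at least 0.2. With the leukocyte covariate the M1-like and M2-like medians turned, to -0.104 and -0.088 under PBS and -0.334 and -0.103 under cisplatin.

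In 9 lists no contrast was called. They were the Pros1 axis, DNA crosslink and excision repair (medians from -0.05 to 0.04), fibroblasts and matrix (-0.20 to -0.02), and endothelium and angiogenesis (-0.04 to 0.12). The others were oxidative stress and metallothioneins (-0.07 to 0.10), apoptosis (-0.01 to 0.14), EMT and invasion (-0.13 to 0.17), complement and coagulation (-0.12 to 0.44) and senescence-associated secretory genes (-0.54 to 0.55). In that order their smallest adjusted p was 0.196, 0.332, 0.159, 0.754, 0.429, 0.48, 0.252, 0.748 and 0.0699. Median, mean and test differed in sign in 22 of the 170 list results, 0 of which were called. For hypoxia and glycolysis in WT tumours under cisplatin, the median was -0.03 while the test pointed up.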

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

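Tests chosen after the results were seen were those of mitochondrial ribosomal RNA, of the removal of libraries rich in mitochondrial reads, and of the split with the replicate 3 libraries exchanged.

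A library was singled out when it lay far from the other 3 of its group, by Dixon's ratio at the 95% level. This was tested in 364 groups of 4, each for 1 measure, and 23 of them held an outlying library. The same library could be picked out for several measures. Chance alone gives about 1 in 20 groups, or 18.2 here.

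Among library measures, WT PBS 1 held 76.9% mitochondrial reads (others of its group 2.03% to 3.74%). Its score of mitochondrially encoded genes was 16.8 (others 7.68 to 8.72). Haemoglobin reads were 15.5% in WT PBS 2 (others 0.778% to 1.92%) and 6.46% in BdP cisplatin 3 (others 0.002% to 0.152%). The immune checkpoint score was 3.68 in BdP cisplatin 3 (others 2.15 to 2.41). The score of senescence-associated secretory genes was 2.85 in BdP cisplatin 2 (others 3.85 to 3.96).

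Single genes far from their group are given as log2(FPKM + 1). In WT PBS libraries these were H1fx at 2.49 and Ndufa4l2 at 2.50 in replicate 1, Fscn1 at 3.90 in replicate 3 and Gsta4 at 5.90 in replicate 4. In WT cisplatin libraries, Mtss1 was at 2.17 and Slc40a1 at 2.09 in replicate 1. Diras1 was at 1.08, Tyro3 at 2.00, Hgsnat at 6.36 and Adgra2 at 3.65 in replicate 2, and Trbj1-2 at 1.47 in replicate 4, where the other 3 were at 0. That Trbj1-2 value lies near the floor, as very few reads give it in so short a segment. In BdP PBS 4, Sema3f was at 0.90 and Pros1 at 1.16 (Pros1 in the others 1.36 to 1.38). In BdP cisplatin libraries, Diras1 was at 0.087 and Jph2 at 1.60 in replicate 1, Pdcd4 at 4.71 in replicate 2 and Fscn1 at 3.23 in replicate 3.

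The response to cisplatin differed between the genotypes in 9 lists by camera at the preset correlation. The median difference, BdP minus WT, was 0.20 for cell cycle, 0.30 for type I interferon, 1.05 for interferon gamma, 0.06 for hypoxia and glycolysis and 0.31 for oxidative phosphorylation. It was -1.50 for B and plasma cells, -0.77 for neutrophils, -0.43 for NF-kB and inflammatory cytokines and -0.91 for immediate early genes. All 9 had an adjusted p = 1 with an estimated correlation. All had 0.965 after adjustment when treatment labels were permuted within genotype. With any 1 library left out, the cell cycle, B cell, oxidative phosphorylation and immediate early differences stayed called. The B cell difference was -0.84 without WT cisplatin 3, -0.89 without BdP PBS 2 and -0.95 without BdP cisplatin 1, and the immediate early difference -0.46 without WT PBS 1. The interferon gamma difference was lost without WT PBS 3 or BdP PBS 3 (adjusted p up to 0.352). The neutrophil difference was lost without WT PBS 4, WT cisplatin 4 or BdP PBS 2 (up to 0.139), and NF-kB without WT PBS 4 (0.0513). Type I interferon was lost without WT PBS 1 or 3, WT cisplatin 1 or 2, BdP PBS 3 or 4 or BdP cisplatin 3 or 4 (up to 0.96). Hypoxia was lost without WT PBS 2, 3 or 4, WT cisplatin 1 or 3, BdP PBS 2 or 4 or BdP cisplatin 1, 3 or 4 (up to 0.192), with a median of -0.001 without BdP PBS 4.

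Mitochondrial reads filled 76.9% of WT PBS 1. Mitochondrial DNA would cover all mitochondrial genes evenly, but the higher of the 2 ribosomal RNAs reached 9.82% of the length-weighted mean of the 13 protein genes, which argues against DNA as the main source (an earlier test, of the spread between the protein genes, decided nothing). The melanocyte score of 6.97 lay above the other WT libraries (6.57 to 6.96), and Pros1 at 9.77 FPKM lay within theirs (4.79 to 11.5), which argues against another tissue or an exchange with a BdP tumour. Loss of cytoplasmic RNA may have contributed, but 2 transcripts kept in the nucleus went apart: Malat1 was at 7.48 FPKM, below the others (8.85 to 36.9), and Neat1 at 5.05, above them (0.629 to 4.44), so it cannot be told apart from other changes of RNA quality. No biological explanation was tested.

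The interferon gamma score was 1.35 higher in BdP than WT tumours under cisplatin. Host sex as the whole cause is argued against by the smaller of the differences within Xist-positive and within Y-positive libraries, 1.06. Without the libraries rich in mitochondrial reads the difference was 1.52. In WT under cisplatin these were replicates 3 and 4, which were also the Xist-positive ones. Their leukocyte scores were higher (4.54 and 3.49, against 1.92 and 2.86 in replicates 1 and 2). Their removal thus changed sex and leukocyte content too, and cannot decide on mitochondrial reads. Within Y-positive libraries, none of them rich in mitochondrial reads, the difference was 1.06, which argues against these reads as the whole cause. With the leukocyte score as a covariate the difference was 0.257 ± 0.457, or 19.1% of the full value, so a higher leukocyte content of the BdP tumours may account for most of it. Whether low Pros1 draws in the leukocytes, or the tumours differed otherwise, stays open, as leukocyte content and genotype go together here (exact two-sided permutation p = 0.0571).

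Other splits of the samples were fitted to see whether chance groups give as many called genes. Under cisplatin the real split by genotype called 132 genes and was 1 of 35 splits to reach that number, with 1 gene as the highest of the others. This argues against chance but cannot exclude it, since 1 of 35 is the best result possible and several contrasts were tested. Under PBS the real split called 122 genes, and 2 of 35 splits reached that number, so chance cannot be excluded by this count. The other split called 657 genes, several times the real count, and points to a structure of the samples: it puts WT PBS 1, 2 and 4 with BdP PBS 3, which has the lowest leukocyte score of its group (3.58), and WT PBS 3, the highest of its own (5.38), with the other BdP libraries. With the leukocyte covariate that split called 0 genes and the real one 23. The score separates the sides of the exchanged split completely (at most 4.00 against at least 4.37). Loss of its calls was thus likely whatever the cause, and whether leukocyte content sets this structure stays open. Pros1 was lower in each BdP library than in any WT library, which argues against exchanged labels.

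For cisplatin in WT tumours, 2 of 35 splits called at least as many genes as the real one (1 gene, highest other 3), so chance cannot be excluded. In BdP tumours (real 0, highest other 11) and for the interaction (real 0, highest other 2) each split reaches a real count of 0, 35 of 35 and 100 of 100, so these counts decide nothing.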

How the results depend on the processing

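The fits with limma-voom, without the 3 libraries rich in mitochondrial reads (WT PBS 1, WT cisplatin 3 and 4) and with a sex covariate, and the leukocyte covariate for lists, were chosen after the data were seen. The cause was not tested for a change of count unless one is given.

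The Pros1 falls kept their direction in every alternative. They missed the threshold in TPM, at -0.961 (adjusted p = 0.359) under PBS and -1.913 (adjusted p = 0.216) under cisplatin. Under PBS the fall also missed it in a fit on the 8 libraries compared (-1.537, adjusted p = 0.0807). Fewer libraries alone do not account for this, since such fits moved the gene counts in opposite ways. The counts went from 122 to 3 under PBS and from 132 to 251 under cisplatin. The spread was thus larger under PBS, and the 122 calls rest on a spread pooled over all 16 libraries. With array weights Pros1 was called higher under cisplatin in WT tumours (0.854, adjusted p = 0.0297). Leaving out 1 library gave -1.645 to -1.347 under PBS, -1.921 to -1.729 under cisplatin, 0.516 to 0.815 for cisplatin in WT, 0.303 to 0.432 in BdP and -0.458 to -0.160 for the interaction.

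Cisplatin in WT tumours called 1 gene. The count was 0 with either pseudocount, the filter of 5 FPKM, TPM, quantile normalization, the fit on 8 libraries, the muscle covariate and without mitochondria-rich libraries. It was 2 with voom and 24 with array weights. In BdP tumours (0) it was 1 with a pseudocount of 0.1, no filter, array weights, no trend and without mitochondria-rich libraries, and 5 in TPM. The interaction (0) called 1 with no trend and 1 with voom.

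The 122 calls between genotypes under PBS became 56 with no filter (29405 genes tested), 23 with the leukocyte covariate, 50 without mitochondria-rich libraries and 3 in the fit on 8 libraries. TPM called 92 (91 higher, 1 lower, against 51 and 71), shared 6 calls and turned the sign of 42, Rtca among them (0.015). TPM counts mitochondrial reads in each total (76.9% in WT PBS 1, 12.2% and 21.7% in WT cisplatin 3 and 4), so the median of all genes moved by 0.817 there, by 0.703 for cisplatin in WT, by 0.148 for genotype under cisplatin and by -0.651 for the interaction. The 132 calls under cisplatin became 76 with the filter of 5 FPKM (7483 genes), 15 in TPM (4 higher, 11 lower), 251 in the fit on 8 libraries, 943 with array weights (419 higher, 524 lower), 77 with the leukocyte and 7 with the muscle covariate, 240 with voom and 55 without mitochondria-rich libraries. Most genes of the muscle covariate failed the expression filter. Quantile normalization shared 96 and 110 of the calls. Median-of-ratios scaling moved nothing, being in the deposited values already, and tests nothing.

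No pairing by replicate number was seen. Same-number libraries correlated with a median of 0.02 (-0.613 to 0.415) after removing group means, and 1 of 16 matched its own number best. A weaker effect of a shared litter, day or batch cannot be excluded, since larger differences between tumours could hide it. With a replicate block the counts were 0 for cisplatin in WT, 81 under PBS and 80 under cisplatin, and 1 of 58 called lists was lost (hypoxia in the interaction, adjusted p = 0.0602).

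With 1 library left out the counts were 0 to 3 for cisplatin in WT (3 without WT PBS 1, 2 without WT PBS 4), 0 to 1 in BdP (1 without WT PBS 2 or WT cisplatin 4), 25 to 356 for genotype under PBS, 50 to 310 under cisplatin and 0 to 1 for the interaction (1 without WT PBS 4 or BdP cisplatin 4). The M1-like minus M2-like score ran from 0.072 to 0.462 and from -0.197 to 0.040 between genotypes under PBS and cisplatin, from 0.003 to 0.256 and from -0.419 to -0.030 for cisplatin in WT and BdP, and from -0.541 to -0.151 for the interaction. Without WT PBS 1 the immediate early list in WT turned to -0.139 (range up to 0.710), and mitochondrially encoded genes under PBS to 0.311 (range from -2.428). Without WT PBS 3 the type I interferon interaction was -0.007 (range up to 0.636). The median crossed 0, with the test pointing the same way, for checkpoints in WT without WT PBS 3 (0.051), B cells in BdP without BdP PBS 2 (0.025) or BdP cisplatin 1 (0.023) and the hypoxia interaction without BdP PBS 4 (-0.001).

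With 1 library left out, the median moved by over 1.5 times in 45 of 58 called lists. Of the 58, all lost the call with an estimated correlation, 3 with a pseudocount of 0.1 and 0 with the sex covariate. The leukocyte covariate left 34 called, 12 lost and 12 turned. Turned under PBS were type I interferon (-0.224), MHC class II (-0.157), M1-like (-0.104), M2-like (-0.088), T cells (-0.106), cytotoxic effectors (-0.102), NK cells (-0.134), checkpoints (-0.152) and chemokines (-0.279). Turned under cisplatin were M1-like (-0.334, adjusted p = 0.0499), M2-like (-0.103) and dendritic cells (-0.090). Without mitochondria-rich libraries 10 were lost and the direction of the test turned in 4. The medians were -0.278 for NF-kB, -0.367 (adjusted p = 0.000107) for immediate early genes and -0.005 (still below 0) for oxidative phosphorylation for cisplatin in WT, and 0.311 for mitochondrially encoded genes under PBS.

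Depth limits WT PBS 1 most, with 2322202 reads outside mitochondrial genes, followed by WT cisplatin 4 with 9913661. On data simulated with levels and spread from all 4 groups, 66% of 2-fold changes between genotypes under PBS were recovered. In that contrast 12 unchanged genes were called. Changes of that size can thus be missed.

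Of the 78 results for single named genes, TPM left 44 on their side of the threshold with their direction, the leukocyte covariate 59, no filter 60, the muscle covariate 61, the removal of mitochondria-rich libraries 61 and array weights 72. The fit on 8 libraries left 44 and lost 24. In these settings Rtca in TPM was the 1 that turned.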

Other observations

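The comparison of chromosome windows was chosen after the differences between genotypes were seen, as were the genes named in the next paragraph, the window score with a leukocyte covariate and the ratios of mitochondrial genes.

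Among the 39 genes called between genotypes under both treatments were several not yet described. Etv4, an ETS transcription factor (-1.36 under PBS and -0.89 under cisplatin), B4galt2, a galactosyltransferase (-1.07 and -1.08), and Tmeff1 (-0.93 and -1.28) were lower in BdP tumours. Nectin2, an adhesion molecule that receptors of NK and T cells bind (-0.57 and -0.74), and Eif4e, the cap-binding translation factor (-0.47 and -0.40), were lower too. In TPM, which moved the median of all genes by 0.82 under PBS, Nectin2 and Eif4e lay above 0 there (0.26 and 0.47), their changes being smaller than the common shift. Lifr, the receptor of leukemia inhibitory factor (0.76 and 0.72), Pdk2, a kinase of pyruvate dehydrogenase (0.98 and 0.94), and the transcription factor gene Foxo4 (0.45 and 0.53) were higher.

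Differences between BdP and WT tumours moved together along chromosomes. The 263 windows of 40 neighbouring genes held 10434 genes. The median differences under PBS and under cisplatin correlated across windows with r = 0.771. The 262 circular shifts along the genome gave at most 0.598, and the 2 cisplatin contrasts gave 0.011. Chromosome 3 was at 0.91 of the WT level at its median under PBS and 0.871 under cisplatin, and chromosome 18 at 1.15 and 1.21. On chromosome 8 the shift ended within the chromosome, with a median of 0.23 up to 84000409 and -0.02 from 84030294 under PBS. On chromosome 1 the 7 windows from 127868773 to 191318194 were higher, at 0.16 to 0.38 under PBS and 0.15 to 0.28 under cisplatin. Chromosome 17 was at -0.09 under PBS and -0.18 under cisplatin.

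GC content and gene length are argued against as the cause, since r was 0.785 after their trends were removed. With the leukocyte covariate r was 0.784. Both contrasts then share the same estimated leukocyte slope for each gene, and its error can make them correlate, so this r does not decide on leukocyte content. A candidate explanation is a difference in DNA copy number between the BdP and WT cell lines. Some stretches shifted under cisplatin alone, which a fixed difference of this kind would not give. Windows of chromosome 10 from 93523338 ran from -0.205 to -0.146 under cisplatin and from -0.095 to 0.023 under PBS. Those of chromosome 13 from 30813919 ran from -0.136 to -0.059 and from -0.059 to 0.071. These stretches were picked after the values were seen and were not tested. When 53 windows and their signs were chosen from the PBS libraries alone, the score in the cisplatin libraries was 0.141 ± 0.025 in BdP and -0.055 ± 0.048 in WT tumours (n = 4, exact two-sided permutation p = 0.0286, the smallest possible). The lowest BdP library (0.113) lay above the highest WT library (0.003), but the score also rose with leukocyte content (0.039 ± 0.007 per unit), which took the difference from 0.196 to 0.129 ± 0.017 as a covariate. This stays a hypothesis, since RNA does not measure copy number, and an effect of low Pros1 on these segments was not tested.

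The share of mt-Co2 differed in the libraries rich in mitochondrial reads. mt-Co2 measured 26.2% of the mt-Co1 FPKM in WT PBS 1, 15.6% in WT cisplatin 4 and 5.68% in WT cisplatin 3, against 1.07% to 3.75% in the other 13 libraries. mt-Atp6 measured 25.5%, 17.5% and 4.78% of mt-Co1 in these 3 libraries, but 14% in BdP PBS 3 as well. mt-Co3 measured 21.6%, 5.72% and 4.31%, against 5.05% in BdP cisplatin 3. mt-Cytb measured 84.8% in WT PBS 1 but 61.7% and 50% in the other 2, near the 51.9% to 72.8% of the rest.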
